A study of Mus musculus with 6 samples.

How the data were processed

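The series holds RNA-seq of mouse B-cell acute lymphoblastic leukaemia. Per the labels, mice received fetal liver progenitors carrying N-Myc and a GFP reporter, and leukaemic mice were left fed or were fasted for 1 or 2 days. GFP-positive cells bearing the B220 form of CD45 were sorted from bone marrow. There are 3 groups (fed control, 1-day fasted, 2-day fasted) with 2 deposited libraries each, titled replicates 1 and 2 and called run 1 and run 2 here. The number of mice behind each library is not stated in the labels.

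The authors' files give, for each gene, read counts in several classes (total or unique, over the whole gene, exons, exon junctions and introns). The RPKM values were also computed by the authors before they were deposited and were used here only as an alternative unit. Reads were aligned with TopHat2 to mouse build mm10, per the submitters' processing notes. The counting program and the annotation are not given in the sources used here. Gene positions overlapped those of a reference mouse annotation for 99.9% of 35348 named genes. Whether counting used strand is not stated, so reads of antisense or overlapping genes cannot be told apart. Values of near-identical copies (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Hspa1a and Hspa1b, Vpreb1 and Vpreb2, immunoglobulin segments, MHC genes) are uncertain, since reads can be shared between them.

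Run 1 lists 38355 genes and run 2 lists 38924, so the runs were counted with different gene tables. Genes were joined by position (37437) or by name and chromosome (296), giving 37733 genes. These hold 99.95% to 99.96% of gene reads in run 1 and 95.45% to 97.32% in run 2. Mitochondrially encoded genes are listed in run 2 and not in run 1, and they were left out of the gene counts and lists. Their run 2 values stand only in the closing section.

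Both libraries of a group were compared before any test. A squared difference between runs, divided by its read-sampling variance, has a median ratio near 1 when the runs are draws from one RNA pool. On unique gene reads it was 1.101 to 1.105 within groups and 5.90 to 18.5 between groups. On unique reads, genes more than 3 SD apart made up 0.889% to 1.04% within groups, where chance gives 0.27%. On total gene reads, which the comparisons use, the median ratio was 1.34 to 1.37 within groups, with 3.94% to 4.58% of genes more than 3 SD apart. Simulated pairs whose genes vary by 5% per replicate gave 2.59 to 2.80, and pairs with no such variation gave 1.00 to 1.03. Averaged over genes, the ratio is the planned chi-square per degree of freedom. Within groups it was 3.21 to 4.40 on unique and 13.2 to 16.0 on total gene reads. Without genes 5 SD or more apart it was 1.095 to 1.103 and 1.506 to 1.559. The runs of a group therefore agree within sampling noise for most genes but not for all, and each group was counted as 1 sample (n = 1). Counting runs that agree within sampling noise as 1 sample was fixed before the data were examined. The median as the measure of agreement was not part of that plan. Also fixed before were the gene lists, the comparisons, most alternatives and the test that was replaced, an edgeR quasi-likelihood test with runs as replicates. No p-value across genes is given, and no difference between groups has a replicate check.

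Total gene reads per library were scaled to CPM (counts scaled to a common library size) with TMM factors from edgeR 4.0.16 in R 4.3.3. A group's level is the mean CPM of its 2 runs. The log2 fold is that of the means, with 0.1 CPM added to each. Genes kept by filterByExpr with a minimum count of 10 numbered 14236. A gene is counted as differing when its mean and each run showed at least a 2-fold difference in the same direction, a rule chosen after seeing the data because no test applied. Members of gene lists were counted at 1.5-fold on the same terms. On simulated counts for the 1-day comparison with control, 99 of 100 genes set 3-fold apart were recovered, and 0 of 100 set 1.5-fold apart. In that simulation 1 of 14036 unchanged genes was counted. In the simulated 2-day comparison with control, in which no gene differed, 9 of 14236 were counted.

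Each gene list's median log2 fold was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list is called when it lies outside their central 95%. The percentile describes these libraries and carries no p-value. It replaces the planned limma camera test and was chosen after seeing the data. Of 45 lists, 42 had at least 5 measured genes. The lists of liver transcripts (1 gene), megakaryocytes and platelets (4) and mitochondrially encoded genes (0) had fewer and were not scored.

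In each comparison and direction, the text names the 10 genes with the largest absolute log2 fold among those counted as differing, with a mean of at least 5 CPM. Provisional gene models and immunoglobulin segments were counted but not named by this rule. It also names up to 4 members per list. The planned rule took list members by p, which was replaced by the largest absolute log2 fold. Mycn, Myc, Lepr, Lep, Prdm1 and Ptprc are always given. Some genes that this rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

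Intervals on ratios of reads are exact 95% conditional binomial intervals. They cover counting error only, since reads amplified by PCR are not independent molecules. Where a library pool had 0 reads, its floor was taken as 3 counts over the 2 runs of the group. Alternatives were DESeq2 1.42.0 size factors, library totals, other filters, unique or exon reads, RPKM, other pseudocounts and folds, each run left out, and the runs entered as replicates in edgeR, DESeq2 and limma 3.58.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used for the rest.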

Results

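Gene expression was measured by RNA-seq in sorted N-Myc-driven B-cell leukaemia cells from bone marrow of fed mice and of mice fasted for 1 or 2 days. Each of the 3 groups has 2 libraries, titled replicates 1 and 2, which agree within sampling noise for most genes and were counted as 1 sample with 2 runs. Total gene reads in run 1 and run 2 were 23412288 and 43785874 in control, 28805008 and 45862844 at 1 day, and 36627712 and 19368326 at 2 days. No difference between groups has a replicate check. For named genes with at least 100 reads in both groups, the log2 folds of run 1 and run 2 differed by a median of 0.07 in each comparison with control, and by at most 0.80 at 1 day and 0.78 at 2 days. Members of gene lists are called higher or lower where they differed by at least 1.5-fold in the mean and in each run.

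Transcripts of the driving oncogene and of the gene of the sorting antigen were at similar levels in the 3 groups. Mycn, the oncogene that started the disease, stood at 2180 CPM in control, 2110 CPM at 1 day and 2280 CPM at 2 days, log2 folds of −0.05 and 0.06 against control. Its locus spans 12936096 to 12941914 on chromosome 12 of mm10, and 100% of its gene reads were exonic, so transgene and endogenous transcripts were not separated. Ptprc, the CD45 gene, which encodes the B220 antigen used for sorting, was at 185, 197 and 186 CPM. Its reads were counted over the whole gene, so the B220 form was not measured apart from other CD45 forms. All samples were sorted on B220, which may itself make these levels alike. Myc itself had few reads, 22, 48 and 48, giving ratios to control of 1.94 (1.15 to 3.38) at 1 day and 2.53 (1.5 to 4.4) at 2 days.

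The first comparison, 1-day fasted against control, asks how the transcriptome of the leukaemia cells differs after a short fast. Bcl2, the anti-apoptotic mitochondrial protein, was higher, at 19.5 CPM against 1.86 (log2 fold 3.32; 3.51 in run 1 and 3.15 in run 2). The lists of mature B-cell and MHC class II genes had higher medians, as had immediate early genes, which respond to stimuli, tissue handling among them, without new protein synthesis. Dntt, whose product adds nucleotides at V(D)J junctions in immature lymphocytes, was lower, at 20.7 CPM against 75.9 (log2 fold −1.87; −1.91 and −1.83). Of 14236 genes, 213 were higher and 111 lower by at least 2-fold in both runs.

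Lmna, encoding the nuclear lamins A and C, stood at 47.1 CPM against 5.53 in control (log2 fold 3.07), and the stress-induced transcription factor Atf3 at 20.2 against 2.47 (2.99). The calcium-binding proteins S100a4 (2.72) and S100a6 (2.59), the actin-binding villin homologue Vill (2.66), Tmeff1 (2.66), the inflammatory caspase Casp1 (2.56) and the zinc-finger gene Zbtb32 (2.37) were also higher. Mtmr7, a phosphoinositide phosphatase gene on chromosome 8 (40551095 to 40634797), had the largest log2 fold among the genes the naming rule takes, at 5.27. Only 0.39% of its reads at 1 day were exonic, and on exon reads its log2 fold was 0.01. Pan3, a subunit of an mRNA deadenylase, was at 143 CPM against 729 in control (log2 fold −2.35). Lower too were the desmosomal cadherin Dsg2 (−1.59), Plekha8 (−1.47), the BMP signal transducer Smad1 (−1.46), the methylcytosine dioxygenase Tet1 (−1.34), the ephrin receptor Epha2 (−1.32), the nuclear envelope protein Syne2 (−1.30), Pkp4 (−1.23) and the auxilin Dnajc6 (−1.22).

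Among B-lineage lists at 1 day, mature and follicular B-cell genes had a median log2 fold of 0.75 (percentile 100 among matched random lists), with 10 of 19 members higher and 0 lower. Examples were the lambda constant segment Iglc2 (1.66), the follicle-homing receptor Cxcr5 (1.56), the complement regulator Cd55 (1.15) and the CD20 gene Ms4a1 (1.14). MHC class II presentation had a median of 0.58 (percentile 100), with 6 of 13 members higher and 0 lower. The invariant chain Cd74 stood at 817 CPM against 422, H2-DMb1 at 24.9 against 12.8 and the costimulatory ligand Cd86 at 13.7 against 6.62. Early B-cell progenitor genes had a median of −0.22 (percentile 0), with 4 of 20 lower and 1 higher. Besides Dntt, the lower members included Kit (−1.53), the stem cell factor receptor, and Arpp21 (−0.93), while the cytokine receptor Flt3 was higher (0.85). The list of B-lineage transcription factors and surface proteins had a median of 0.06 (percentile 99.3; 3 of 26 higher, 0 lower), with the kinase gene Blk (1.01) and the adaptor Bank1 (0.95) above 1.5-fold and Lef1 at −0.61. Plasma cell genes had a median of 0.12 (percentile 98.0), with 2 of 16 higher and 1 lower, while the J-chain gene Igj was at −1.18 and Sdc1 at −0.65.

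Markers of other marrow cells differed in the same libraries. Neutrophil genes had a median of −0.35 (percentile 0), with 5 of 24 lower and 0 higher, S100a8 being at 112 CPM against 180 and lactoferrin Ltf at 81.9 against 138. T-cell and NK-cell genes had a median of 0.29 (percentile 99.6), with 10 of 26 higher and 2 lower, the higher ones including Ncr1 (2.21), Klrb1c (2.00) and Klrd1 (1.37), all at 1.14 CPM or less. Stem and myeloid progenitor genes had a median of 0.34 (percentile 99.7), with run medians of 0.68 and 0.25. Of 17 members, 5 were higher and 2 lower, the higher ones including Gata2 (1.43), Egr1 (1.46) and Lmo2 (1.75). Egr1 is also in the list of immediate early genes. On exon reads the Lmo2 fold was 0.09, and 27.7% of its reads were exonic at 1 day against 87.7% in control. Erythroid genes (0.04), monocyte and dendritic cell genes (0.19) and stromal genes (0.00) lay within the central 95%.

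Several signalling and stress lists were called at 1 day, most of them higher. Immediate early genes had a median of 0.76 (percentile 100), with 17 of 26 higher and 0 lower, including the orphan nuclear receptor Nr4a1 (13.5 to 42.8 CPM), the phosphatase Dusp5 (23.7 to 68.3) and Klf6 (16.0 to 45.8). That list was drawn up as a quality list, since cell isolation and sorting also raise these genes, and handling was not tested. Glucocorticoid response genes had a median of 0.16 (percentile 100), with 8 of 31 higher and 0 lower. Tsc22d3, the classic glucocorticoid-induced leucine zipper, stood at 195 CPM against 94.3, and the pro-apoptotic Bmf at 13.1 against 3.50. The ATF4 amino acid response (0.17, percentile 100) had 11 of 41 higher and 1 lower, the higher ones including Chac1 (1.39) and the glycine transporter Slc6a9 (1.10). NF-kB and inflammatory genes had a median of 0.25 (percentile 100), with 6 of 26 higher and 0 lower, including Ccl5 (2.36), Ccl3 (1.35) and Cd40 (1.25). These examples had low levels, at 1.24, 0.505 and 2.93 CPM at 1 day, and Ccl5 is also in the T-cell and NK-cell list. Endoplasmic reticulum stress genes had a median of 0.18 (percentile 100), though 0 of 29 reached 1.5-fold. Homing and adhesion genes had a median of 0.17 (percentile 100), with 5 of 21 higher and 1 lower, the gut-homing integrin Itgb7 being at 65.2 CPM against 26.2. Type I interferon genes had a median of −0.12 (percentile 0.41), with 3 of 41 lower and 0 higher, Isg15 being at −0.85 and Oasl1 at −0.80.

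Growth and metabolism lists differed little at 1 day. G2/M genes had a median of −0.20 (percentile 0; 1 of 55 lower) and G1/S genes of −0.11 (percentile 0.01; 0 of 48), with the proliferation marker Mki67 at 919 CPM against 1230 and Cenpf at 127 against 187. Cell cycle inhibitors and quiescence genes had a median of 0.17 (percentile 99.9), with 4 of 23 higher and 0 lower, including Cdkn1c (1.56), Klf4 (1.40) and the p21 gene Cdkn1a (1.07). MYC targets had a median of −0.03 (percentile 45.6), with 0 of 62 higher and 2 lower, Sord (−0.84) and Ccnd2 (−0.74). Ribosome biogenesis (−0.01, percentile 64.9) had 0 of 57 past 1.5-fold, and cytosolic ribosomal proteins were at 0.12 (percentile 100) with 0 of 85. Oxidative phosphorylation had 0 of 81 members past 1.5-fold (percentile 79.3). Glycolysis (percentile 61.5), cholesterol synthesis (90.6), fatty acid synthesis (8.87), fatty acid oxidation (23.9), FoxO targets (27.8) and autophagy (59.9) also lay within the central 95%. Insulin, IGF and mTOR signalling was called at a median of −0.09 (percentile 0.83), though 3 of 35 members were higher and 1 lower and the mean was −0.02, with the IGF receptor gene Igf1r at −0.92 and the mTOR inhibitor Ddit4 at 0.77.

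In all, 20 of 42 lists were called at 1 day, 14 above and 6 below. If list members varied independently, as genes drawn at random are taken to do, 2.1 would lie outside. Lists whose genes vary together can lie outside more often, and some lists share members. The value of 2.1 is therefore not a chance expectation for these lists. The interquartile range of log2 folds over 11741 genes at 1 CPM or more was 0.275, against 0.0887 to 0.104 between runs of a group, and the SD, which rests on the tails, was 0.359 against 0.302 to 0.338. The count of differing genes depended on low-level genes: it was 122 with a minimum of 5 CPM and 109 with a pseudocount of 1 CPM. It was 636 without control run 2 and 572 without 1-day run 2, where a single run then had to pass.

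**Figure D1:**
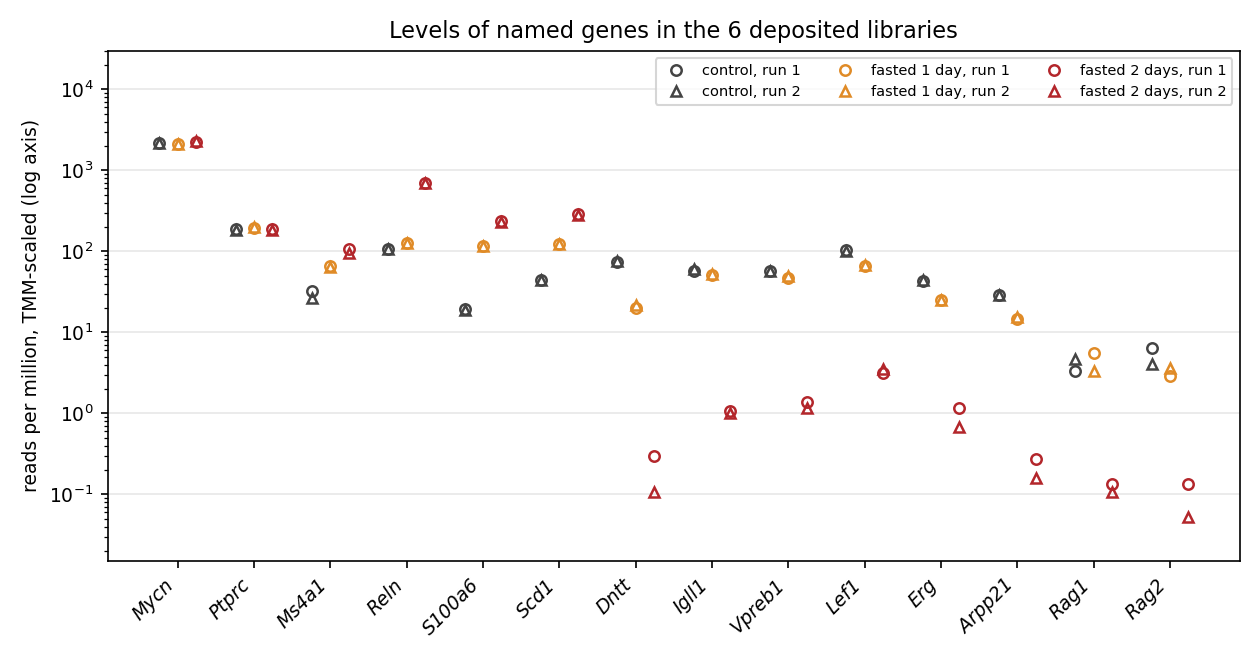
CPM on a log axis of selected genes in control, 1-day and 2-day fasted samples, with a point per run. Dntt lies at 75.9 CPM in control, 20.7 at 1 day and 0.20 at 2 days, while Mycn stays between 2110 and 2280 CPM.

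The next comparison, 2-day fasted against control, addresses a longer fast. Of 20 early B-cell progenitor genes, 15 were lower and 3 higher. Dntt had 13 reads in the 2-day sample against 4951 in control, 0.20 against 75.9 CPM (log2 fold −7.98; −7.56 in run 1 and −8.55 in run 2). Igll1, encoding the surrogate light chain lambda5, was at 1.03 CPM against 58.7 (−5.70). Of 19 mature B-cell genes, 12 were higher and 3 lower, with Ms4a1 at 99.9 CPM against 29.2 (1.77), while of 13 MHC class II genes 7 were lower and 3 higher, with H2-Eb1 at 52.2 CPM against 150 (−1.52). The immediate early gene Ier2 stood at 247 CPM against 21.6 (3.51; 3.56 and 3.46). Of 14236 genes, 635 were higher and 813 lower by at least 2-fold in both runs.

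Among the genes the naming rule takes, the largest fold upward was that of Cd6, a lymphocyte scavenger-receptor protein encoded on chromosome 19 (10789341 to 10830058), at 26.9 CPM against 0.677 (log2 fold 5.12; 4.91 and 5.36). The leukaemia inhibitory factor receptor Lifr (3.89), the carboxypeptidase N subunit Cpn1 (6.30 to 94.6 CPM), the Ras-association gene Rassf6 (3.67), S100a6 (19.1 to 234 CPM), S100a4 (3.30), Nr4a1 (13.5 to 154 CPM) and Syndig1l (3.07) were also higher. Tex21 was counted among them at 3.59, but 0% of its reads were exonic.

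Several genes lost nearly all their reads in the 2-day sample. Tmem132e was at 0.0804 CPM against 53.7 (5 reads against 3503, log2 fold −8.22). The aminopeptidase Enpep, the BP-1 antigen of early B cells, was at 0.398 CPM against 75.1 (−7.24), and the GDNF coreceptor Gfra1 at 0.320 against 57.7 (−7.10). Ccdc135 (−7.61), Uaca (−6.76) and Arpp21 (−6.52) were lower too. Fcrl6, an Fc-receptor-like gene, had 0 reads against 704, at least 202-fold lower. Dsg2 had 1 read against 1123, a ratio of 968 (173 to 38300), and Armcx4 had 2 against 797, a ratio of 343 (94.8 to 2840). Across the 3 samples, 91 genes were at least 8-fold lower in the 2-day sample than in both others in every run, against 0 for control and 0 for the 1-day sample.

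Early B-cell progenitor genes had a median log2 fold of −1.33 at 2 days (percentile 0), with 15 of 20 lower and 3 higher. Besides Dntt, Arpp21 and Igll1, the ETS factor Erg was at 0.923 CPM against 44.1 (−5.43). The recombinase genes Rag1 and Rag2, also held by the FoxO target list, were at 0.120 and 0.0939 CPM against 4.01 and 5.21 (−4.22 and −4.78). Mature and follicular B-cell genes had a median of 0.83 (percentile 100), with 12 of 19 higher and 3 lower, including Iglc2 (2.87) and Cd55 (26.8 to 109 CPM). The list of B-lineage factors and surface proteins lay within the central 95% (−0.04, percentile 59.4), its members going both ways: Lef1 (−4.89), Bach2 (−1.95) and Cd72 (−1.81) were lower and Bank1 (1.91) higher. MHC class II presentation had a median of −0.68 (percentile 0), with 7 of 13 lower and 3 higher. H2-DMb2 was at −1.26, while the costimulatory Cd86 (1.40) and Cd83 (1.14) were higher. Plasma cell genes lay within (−0.02, percentile 48.6), with Sdc1 (−1.76) and Slamf7 (−1.60) lower and Txndc5 (1.40) and Fkbp11 (1.2) higher.

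Among markers of other cells at 2 days, T-cell and NK-cell genes had a median of −0.57 (percentile 0.01), with 12 of 26 lower and 4 higher. The lower ones included Lat (6.34 to 0.8 CPM), Tcf7 (6.50 to 0.999) and Cd247 (37.6 to 8.19). Cd6, described above, is also a member of this list and was among the higher ones. Monocyte and dendritic cell genes had a median of 0.51 (percentile 99.6), with 6 of 19 higher and 1 lower, the higher ones including Ccr2 (1.58), F13a1 (1.57) and Csf1r (1.29). Erythroid genes had a median of 0.27 (percentile 97.7), with 6 of 22 higher and 0 lower, the globin Hbb-bs being at 402 CPM against 151 and Alas2 at 10.4 against 3.56. Neutrophil genes (0.14, percentile 90.6), stromal genes (0.28, percentile 89.3) and stem and myeloid progenitor genes (−0.09, percentile 27.9) lay within the central 95%. Lmo2 was at 11.8 CPM against 77.9 (−2.72).

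Homing and adhesion genes had a median of 0.39 (percentile 100), with 7 of 21 higher and 1 lower, Itgb7 being at 146 CPM against 26.2 and Ccr7, a lymph node homing receptor, at 71.7 against 31.1. NF-kB and inflammatory genes had a median of 0.41 (percentile 99.9), with 9 of 26 higher and 1 lower, Bcl3 being at 2.07. Immediate early genes had a median of 0.33 (percentile 100) with 11 of 26 higher and 5 lower, Rhob (−2.11) among the latter. Glucocorticoid response genes had a median of 0.22 (percentile 99.6), with 6 of 31 higher, including Bmf (3.50 to 21.4 CPM), and 4 lower. Apoptosis regulators had a median of 0.18 (percentile 98.6), with 5 of 27 higher and 3 lower. Bcl2 was at 5.53 CPM against 1.86 (1.52), and the pro-apoptotic Bok was lower (−3.52). Autophagy and lysosome genes had a median of 0.15 (percentile 99.7), with 9 of 56 higher, including the lysosomal hexosaminidase Hexa (1.32), and 3 lower, including Rragd (−3.46) and Bnip3 (−1.82). Type I interferon genes had a median of −0.21 (percentile 0.25), with 7 of 41 lower, including Oas1a (−3.87) and Oasl1 (−2.63), and 1 higher. The ATF4 response (0.08, percentile 96.3) and endoplasmic reticulum stress genes (−0.01, percentile 66.2) lay within.

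Cell cycle lists had medians of −0.29 for G2/M (percentile 0) and −0.26 for G1/S (percentile 0) at 2 days, though 2 of 55 and 3 of 48 members passed 1.5-fold, all lower. Mki67 stood at 835 CPM against 1230, Uhrf1 at 432 against 711 and Ncapd2 at 400 against 651. Replication-dependent histones, drawn up as a quality list, had a median of −0.42 (percentile 0.74; 4 of 23 lower), with run medians of −0.52 and −0.33. Some members had low levels in control, such as Hist2h4 at 0.281 and Hist1h4c at 0.377 CPM, while Hist1h2bc was at 38.9. Quiescence genes lay within (0.12, percentile 88.7), with the Cdkn2a gene at −2.32. MYC targets were called at a median of 0.03 (percentile 98.2), with 1 of 62 higher and 2 lower, while their mean was −0.03. Ribosome biogenesis (0.08, percentile 99.8) had 0 of 57 past 1.5-fold, and ribosomal proteins (0.13, percentile 100) had 0 of 85 past it. Oxidative phosphorylation (0.01, percentile 90.6) had 0 of 81 past it. Glycolysis (percentile 46.9), cholesterol synthesis (11.2), fatty acid synthesis (64.0), fatty acid oxidation (20.7), FoxO targets (15.5) and insulin, IGF and mTOR signalling (19.8) lay within the central 95%. Within fatty acid synthesis, the desaturase Scd1 stood at 288 CPM against 44.4 (2.69), while Fads2 (−2.27) and Gpam (−1.33) were lower. Within insulin and FoxO genes, Insr (−0.92) and Igf1r (−1.53) were lower.

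At 2 days 19 of 42 lists were called, 12 above and 7 below, where independent genes would put 2.1 outside, with the same limit as at 1 day. The SD of log2 folds was 0.811, against 0.302 to 0.338 between runs of a group. The mean of a list had the opposite sign to its median in 6 lists at 1 day and 9 at 2 days, 0 and 1 of them called. The count of differing genes was 674 with a minimum of 5 CPM and 842 with a pseudocount of 1 CPM.

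Leptin receptor signalling genes lay within the central 95% at both times, with medians of 0.08 (percentile 86.4) at 1 day and 0.10 (percentile 76.7) at 2 days. Of 16 members, 4 were higher and 0 lower at 1 day, and 5 were higher and 1 lower at 2 days. Irs1 was lower at 2 days, at 0.772 CPM against 1.73 in control. The feedback inhibitor Socs3 was higher in both, at 0.903 CPM in control, 2.60 at 1 day and 6.18 at 2 days, as was the kinase Pim1 at 35.2, 59.1 and 68.3 CPM. The receptor gene Lepr had 5, 5 and 2 reads, with ratios to control of 0.89 (0.205 to 3.87) and 0.464 (0.0442 to 2.84), so that no difference was detectable at this depth. Lep had 0 reads in each sample, which allows up to 0.0462, 0.0411 and 0.0536 CPM. Prdm1, the plasma cell regulator, had 14, 29 and 16 reads, with ratios of 1.84 (0.943 to 3.78) and 1.33 (0.607 to 2.93).

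**Figure D2:**
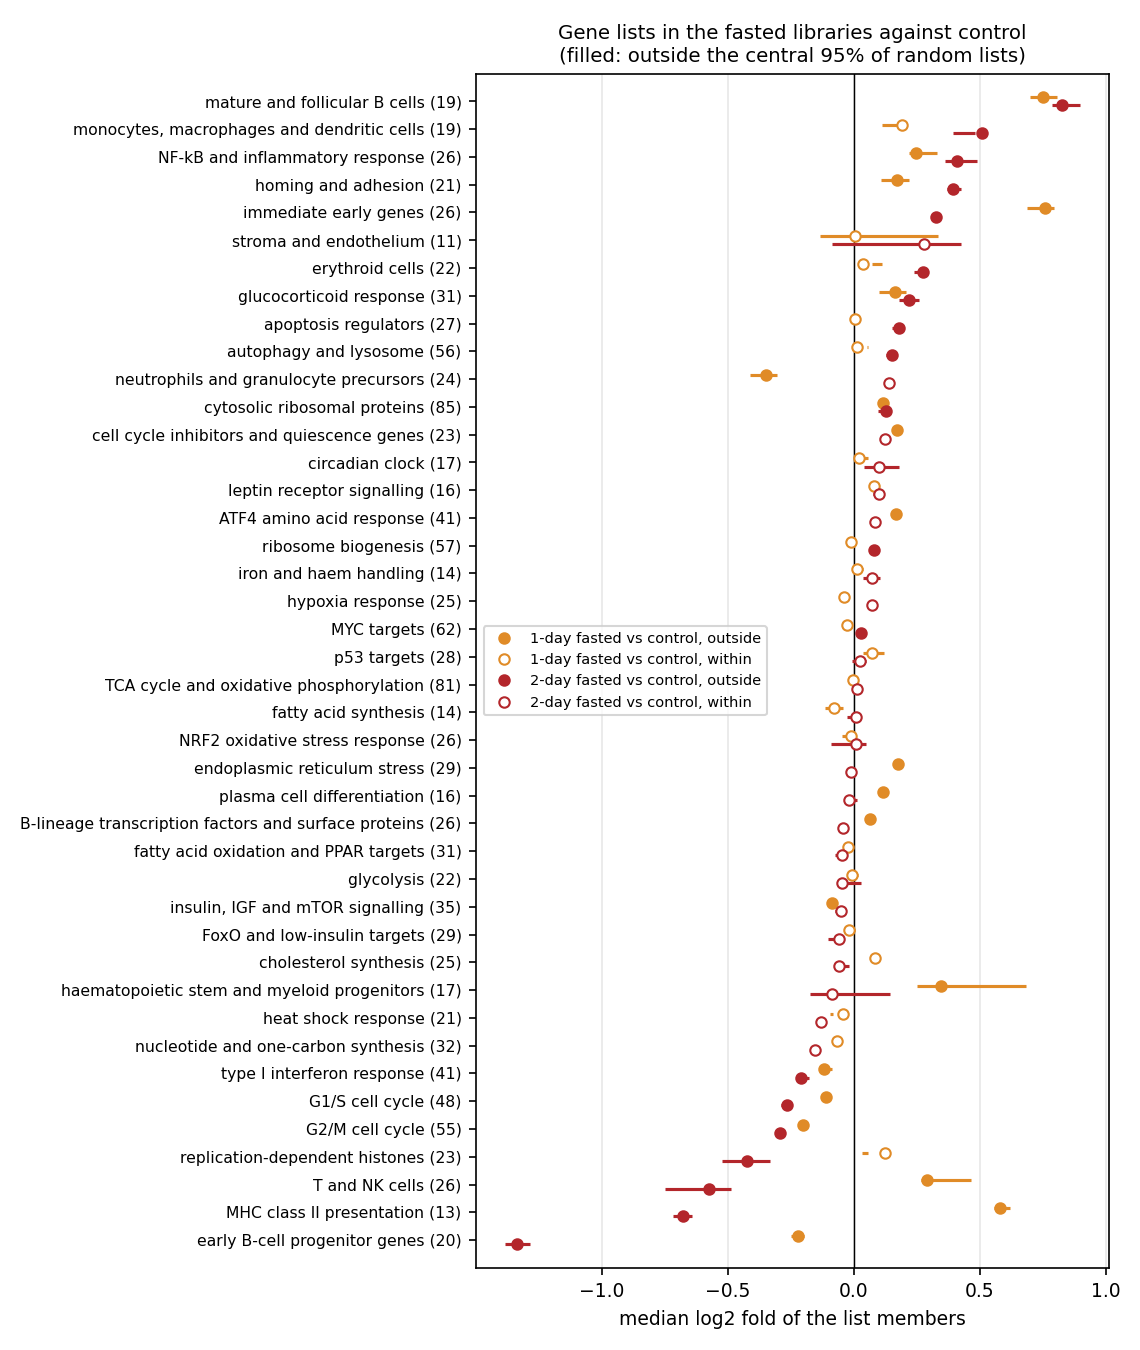
Median log2 fold of each gene list's members at 1 day (orange) and 2 days (red) against control, with lines joining the medians of run 1 and run 2 and filled points outside the central 95% of matched random lists. Early B-cell progenitor genes lie at −0.22 and −1.33, and MHC class II genes at 0.58 and −0.68.

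The 2-day and 1-day fasted samples were compared with each other. With 1 sample each, a second day of fasting cannot be told apart from other differences between the samples, a leukaemia clone among them. Early B-cell progenitor genes were lower in the 2-day than in the 1-day sample, with a median of −0.77 (percentile 0), 12 of 20 lower and 3 higher. Igll1 was at 1.03 CPM against 52.0 (−5.53; −5.47 and −5.59), and its partner Vpreb1 at 1.27 against 48.1 (−5.14). MHC class II genes had a median of −1.05 (percentile 0), with 9 of 13 lower and 0 higher, Cd74 at 299 CPM against 817. T-cell and NK-cell genes had a median of −1.28 (percentile 0), with 18 of 26 lower and 1 higher. Of 14236 genes, 278 were higher and 675 lower by at least 2-fold in both runs.

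Higher at 2 days than at 1 day were Cd6 (5.86), the nicotinic receptor subunit Chrna9 (3.34), Ier2 (2.76), the Wnt receptor Fzd7 (2.64), the basement membrane protein Nid2 (2.59) and the extracellular glycoprotein Reln (127 to 697 CPM). Igj (2.22), Rassf6 (2.19), the calcium release channel Ryr2 (2.18) and the sialic acid hydroxylase Cmah (2.07) were higher too. Lower were Ccdc135 (−7.58), Tmem132e (−7.51), the tissue factor pathway inhibitor Tfpi (27.5 to 0.133 CPM), Enpep (−6.54), Uaca (−6.15), Dntt (−6.11), the peptide transporter Slc15a2 (−6.07), Gfra1 (−5.89) and the adhesion receptor Gpr56 (−5.89). Fcrl6 had 0 reads against 510, at least 130-fold lower.

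Immediate early genes were lower at 2 days than at 1 day in the median (−0.33, percentile 0), with 12 of 26 lower and 4 higher. Fosb was at 52.2 CPM against 342 (−2.71) and Atf3 at 6.00 against 20.2 (−1.74). Asparagine synthetase Asns was at 8.47 CPM against 23.5 (−1.46), within an ATF4 list at percentile 6.43. Bcl2 was lower (−1.80). The median of mature B-cell genes was 0.29 (percentile 100) and their mean 0.10, with 5 of 19 higher and 4 lower, Cd38 being at 22.1 CPM against 7.85 and Faim3 lower (−1.47). Neutrophil genes had a median of 0.54 (percentile 100), with 8 of 24 higher and 0 lower, monocyte genes of 0.41 (percentile 99.6), with 7 of 19 higher and 1 lower, and homing genes of 0.26 (percentile 100), with 2 of 21 higher and 1 lower. Chi3l3 was at 129 CPM against 56.5 and Lyz2 at 104 against 59.7. Replication-dependent histones, the quality list with some low-level members, had a median of −0.64 (percentile 0.03), with 6 of 23 lower. In all, 19 of 42 lists were called, 9 above and 10 below. The count of differing genes was 404 with a minimum of 5 CPM and 465 with a pseudocount of 1 CPM.

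**Figure D3:**
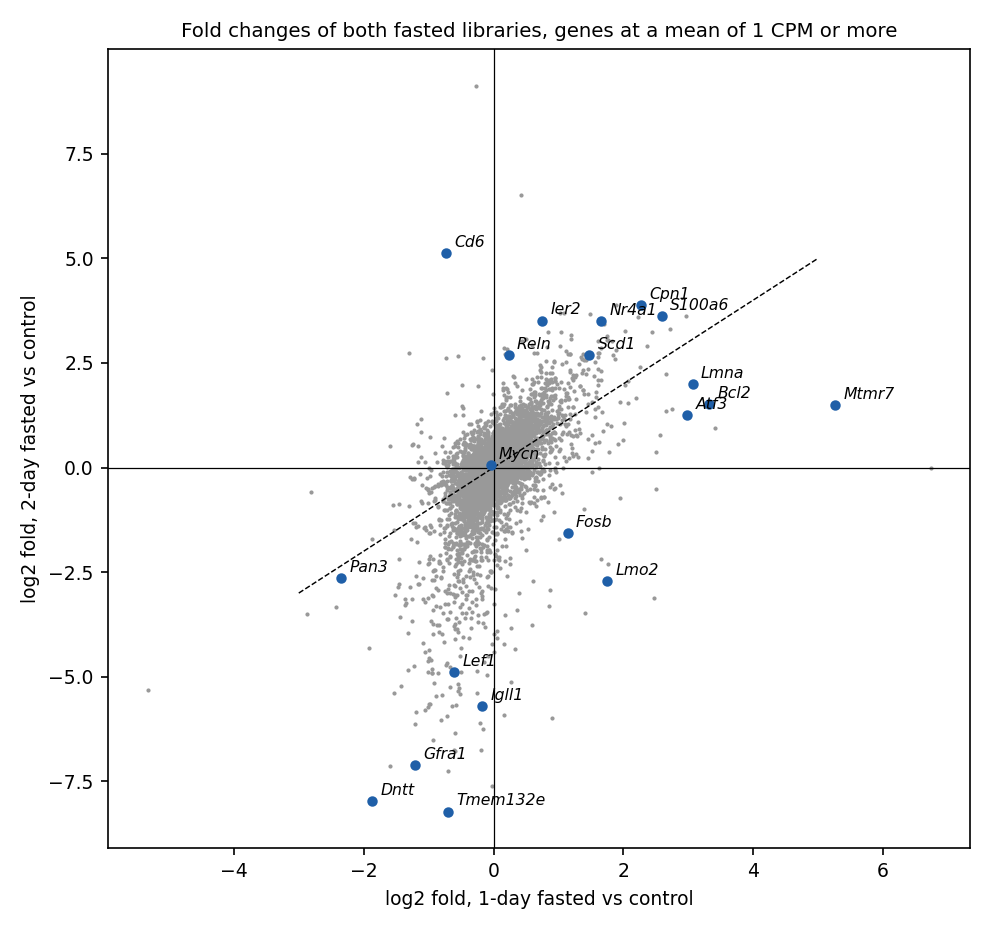
Log2 fold against control of each gene at 1 day (horizontal axis) and at 2 days (vertical axis), for 11741 genes at a mean of 1 CPM or more. Pearson's r across genes is 0.577, and the early B-cell gene Dntt lies at −1.87 and −7.98; named genes are blue and the dashed line marks equal folds.

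Differences at 1 and 2 days were set side by side, both being measured against the same control. Among genes counted as differing, 133 were higher in both comparisons with control and 78 lower in both, where independent lists would share 9.5 and 6.34. In opposite directions, 6 were higher at 1 day and lower at 2 days and 2 were the reverse, where independent lists would share 12.2 and 4.95. Unchanged groups simulated against the same control reads shared at most 1 gene in any of these classes over 100 draws. Independent lists leave out the shared control and the simulation leaves out real differences, so neither is the value expected without a common effect. With the 2-day sample as the shared reference instead, control and the 1-day sample were both higher in 561 genes and both lower in 203, and with the 1-day sample as reference the counts were 14 and 38. Log2 folds at 1 and 2 days correlated across 11741 genes at r = 0.577, although genes are not independent replicates. Unchanged groups simulated against the same control reads gave 0.492 (0.451 to 0.518), with a covariance of 0.00391 against 0.168 observed. With a different run for each comparison r was 0.474 to 0.512. That simulation holds read-sampling noise only, and with 1 control sample part of the excess may come from the control itself. Of 1698 genes that differed in any comparison, the 1-day sample lay between the others in 1273 (75%). The control did so in 306 (18.0%) and the 2-day sample in 119 (7.01%). Each would take 33.3% only if no sample stood further apart than the others. The 2-day sample did, differing from control in 1448 genes and from the 1-day sample in 953, against 324 between control and the 1-day sample. The 33.3% is therefore not the value expected without a graded effect.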

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

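All tests in this part were chosen after the results they weigh were seen. No difference between the 1-day and 2-day samples was tested, since each group has 1 sample.

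In the 2-day sample, 91 genes stood at least 8-fold lower than in both other samples, among them Dntt, Igll1, Vpreb1, Rag1 and Rag2. Replacement of leukaemia cells by others in the sort is argued against by Mycn at a log2 fold of 0.06, when the genes' median was −4.85, and reads shared with near-identical copies by a median of −4.95 on unique reads. What stays open is a leukaemia clone other than that of the control: immunoglobulin V segment reads of the 2-day sample differed from control by a chi-square per degree of freedom of 5.39 and 6.62 in the runs, against 3.06 and 3.47 at 1 day and at most 2.07 between runs of a group. With 1 sample per group and separate animals, a clone difference and an effect of fasting cannot be told apart, and loss of the early B-cell programme with fasting may be held only as a hypothesis.

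The median of mature B-cell genes was higher in both fasted samples: of 19 genes measured among the list's 22, 10 were higher and 0 lower at 1 day, and 12 were higher and 3 lower at 2 days. For the 2-day sample, the MHC class II list, abundant in normal mature B cells, had a median of −0.68 (Cd74 −0.50). Of its 13 members, 7 were lower and 3 higher. This cannot exclude an admixture of such cells, since control cells also had reads of these genes. A fall in the leukaemia cells could then hide an admixture. For the 1-day sample, an admixture cannot be told apart from a change in the leukaemia cells: the same list was at 0.58 and Ms4a1 at 1.14, while Igkc was at 0.16. A leukaemia clone other than that of the control stays open at 1 day too. Its immunoglobulin V segment reads differed from control by 3.06 and 3.47 per degree of freedom, against at most 2.07 between runs of a group. The GFP gate should remove normal cells, yet each sample held reads of genes of other marrow cells. In control, at 1 day and at 2 days, S100a8 was at 180, 112 and 171 CPM and Hbb-bs at 151, 200 and 402. The gate therefore does not exclude an admixture. An effect that grows with days of fasting is a candidate explanation that stays open. The 1-day sample was the middle one in 75% of differing genes, but any single axis through 3 samples puts one of them in the middle. The 33.3% of equal shares cannot serve as a reference, since the 2-day sample stood furthest from the others.

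The 2 deposited libraries of each group differed little. One RNA sample sequenced in 2 runs is consistent with the highest median ratio of 1.105 on unique gene reads, since simulated replicates that vary by 5% gave at least 2.59. Separate animals that differ by less than that were not simulated.

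Further results went in opposite directions at 1 day and 2 days against control in both runs, and none of these differences was tested. The MHC class II list had medians of 0.58 and −0.68. The T-cell and NK-cell list had medians of 0.29 and −0.57, though several members named above did not change sides in the mean. Ncr1, Klrb1c and Klrd1 were above control at both times, and Lat, Tcf7 and Cd247 were below it at both. Lmo2 was at 1.75 and −2.72, the former at 0.09 on exon reads. The J-chain gene Igj was at −1.18 and 1.04. Igha, an immunoglobulin gene chosen after its values were seen, went the same way. It was at 26.0 CPM in control, 11.9 at 1 day and 58.6 at 2 days. The immediate early gene Fosb was at 1.14 and −1.57. The remaining ones were chosen after their values were seen: Myo18b at 1.76 and −2.31, Cldn4 at 2.48 and −3.11, Igkv17-121 at −1.30 and 2.74, Xlr4a at 1.66 and −2.19, and Esx1 at 1.41 and −3.48.

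Mitochondrially encoded genes, listed in run 2 only and left out of the gene counts and lists, took 4.30% of gene reads in the 2-day library against 3.08% in control and 2.46% at 1 day. The median log2 fold of 15 such genes was 0.45 at 2 days and −0.50 at 1 day, each from 1 library per group. At 1 day the genes ranged from −0.74 to 0.18, with 6 lower and 0 higher by 1.5-fold. At 2 days they ranged from 0.07 to 1.06, with 3 higher and 0 lower.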

How the results depend on the processing

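The pseudocount of 1 CPM, exon reads and the 1.5-fold rule were chosen after seeing the data. Counts of differing genes at 1 day, at 2 days, between the fasted samples and in any comparison were 324, 1448, 953 and 1698 as reported. Each stayed within 1.5 times under DESeq2 size factors, library totals, no filter, unique reads and exon reads. At least 84.6% of the same genes were counted on unique or exon reads. Fewer were counted with a minimum of 5 CPM (122, 674, 404 and 726, fewer genes being tested), with a pseudocount of 1 CPM (109, 842, 465 and 906, folds of low genes being shrunk) and on RPKM with 1 added (70, 479, 254 and 536), which changes the unit, the scaling and the pseudocount together. A 1.5-fold rule gave 1008, 2796 and 2024. Leaving out 1 run gave 469 to 636 at 1 day, where 1 run alone had to pass on one side: 636 without control run 2 and 572 without 1-day run 2. Entering the runs as replicates, at an adjusted p under 0.05 with no fold minimum, gave 5342, 8322, 7046 and 9084 in edgeR's quasi-likelihood test, 3962, 7017 and 5554 in DESeq2 and 5540, 8352 and 7133 in limma-voom. This changes 2 choices together, the spread (here that between runs) and the fold minimum, so their parts in the rise were not separated. The replicate block (run number) gave 5621, 8486, 7313 and 9243 in edgeR. As a mean of within-run folds, the block gave 324, 1448, 953 and 1698, as the counting rule already needs both runs, and with a gene length correction 320, 1447, 946 and 1694. Deviations of same-numbered runs correlated between groups at 0.26 to 0.40. With 2 numbers that share a gene table, this does not pair animals. Called lists numbered 17 to 21 and the correlation of folds 0.491 to 0.617 under the alternatives recomputed for each. With a different run for each comparison the correlation was 0.474 to 0.512. Of 7176 alternative values for named genes, 6651 moved by no more than their counting interval or the gap between runs, 524 moved more, and 1 reversed. Rora at 2 days was at 0.58 on exon reads against −1.84. It had 7 exon reads of 86 gene reads in control and 9 of 14 at 2 days, too few exon reads to give a direction. Camera with an estimated correlation, fry and a fit of only 2 groups were not run, as they rest on the spread between runs. Depth limits genes such as Lepr and Lep.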

Other observations

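Clock genes as a list lay within the central 95% at 1 day (0.02, percentile 58.3) and 2 days (0.10, percentile 77.8), but single members stood apart. Arntl, the BMAL1 partner of CLOCK, was at 83.4 CPM in control, 48.7 at 1 day and 14.9 at 2 days. Per3 was at 2.20, 1.41 and 0.747 CPM in the same order (−1.44 at 2 days). Per1, also in the glucocorticoid list, was at 40.8, 76.0 and 72.5 CPM (0.90 at 1 day). The repressor Bhlhe41 was higher in both fasted samples (0.81 and 1.30). The hour of sampling is not stated in the labels.

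The p53 target list lay within at both times (percentiles 93.3 and 56.4), with the pro-apoptotic Pmaip1 at 6.33, 16.8 and 21.8 CPM and Plk2 at 9.06, 37.1 and 35.7 CPM, while Phlda3 was lower at 2 days (−3.05). The heat shock list lay within (percentiles 28.5 and 13.6), yet the inducible Hspa1b was at 25.4, 38.8 and 3.78 CPM. Hypoxia genes (percentiles 20.6 and 78.5), NRF2 targets (56.0 and 76.2), nucleotide and one-carbon synthesis (7.5 and 3.73) and iron and haem handling (66.9 and 85.5) also lay within the central 95% at 1 and 2 days. Among them, Ak4 was lower at both times (−1.83 and −3.14) and the antioxidant Gpx1 higher at 2 days (0.69).

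A provisional gene model, BC061194, was at 0.077 CPM in control, 0.0463 at 1 day and 98.8 at 2 days, and was chosen after its values were seen.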
